A study of Homo sapiens with 6 samples.

How the data were processed

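RNA from HaCaT cells was measured in 6 samples, 3 untreated and 3 treated with tumour necrosis factor alpha and interferon gamma. Groups were taken from the treatment characteristic of each sample, because the treatment protocol text is the same for all 6 samples. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads from total RNA with an integrity number above 7, fragmented, copied with dUTP in the strand that was later degraded, ligated to adapters with unique molecular identifiers and sequenced as read pairs on an Illumina NovaSeq instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2, edgeR and the genome build GRCh38, without their roles or order. The counting program, the annotation release and the strand setting of the counting were not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so p-values of the gene tests measure only the spread between these samples, which may be technical. Camera with a preset correlation compares the genes of a list with the other genes, so its p-values rest on the spread between genes.

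The deposited table gave counts and FPKM for 36752 genes in each sample, with coordinates and annotation terms, and 0 sample columns were left unmapped. The counts deposited by the authors are whole numbers whose small values pile up at multiples of 4, with 6729 gene and library pairs at 4 counts against 3479 at 3 and 2505 at 5. Values of 1 (6388 pairs) and 2 (6341) were common too, and the cause of the pile-up was not tested. FPKM values, deposited by the authors in the same table, held a constant ratio to the counts for each gene and library over 11361 genes, with a largest log2 deviation of 0.0385 from a common library and length factor. The FPKM therefore carry a total-count scale, and levels are given here as CPM after TMM scaling instead. Floors cover counting error only, and bootstrap intervals cover the spread between genes or loci, taken as independent. Where every untreated library had 0 counts, a lower bound was printed against a floor of 12 counts per library, 3 times 4 in case 4 counts stand for 1 read pair, since a fitted fold change then depends on the prior count.

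Genes were kept by edgeR's filter with a minimum count of 10 and a minimum total of 15, which left 19358 tested and 17394 not tested, 4362 of them without a count in any library. Libraries were scaled by TMM, with factors averaging 1.06 untreated and 0.940 treated, and fitted with edgeR's quasi-likelihood test on treatment alone, with two-sided Benjamini-Hochberg adjustment at 0.05. The design foresaw limma on log2(FPKM + 1) and, if the table held counts, edgeR on those counts instead, so edgeR is the reported test and the limma fit an alternative. The common biological coefficient of variation was 16.8%. Pairs of libraries within a group differed by 2.61 to 6.91 times the chi-square median of counting noise (counts divided by 4), which leaves open whether they are repeat preparations from 1 culture.

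Gene lists (32 lists, 942 genes, 918 of them in the table and 24 not analysed here) were tested with limma's camera at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, where at least 5 members were tested, which held for 31 lists. Annotation terms in the table with 15 to 300 tested members were tested the same way. Each gene symbol that occurs more than once (4445 repeats) was represented by its entry with most counts. Called members of each list are counted after adjustment over all genes tested and adjusted over the list alone. The number of genes at an FPKM of at least 1 was compared by an exact two-sided permutation test.

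The tests, the lists, the alternatives not stated to be added and the rule for named genes were fixed before the data were examined. That rule names IRF1, GBP1, NFKBIA and ICAM1, then the 10 largest rises and 10 largest falls among named genes with an adjusted p under 0.05, FPKM ranges that do not overlap and a mean FPKM of at least 1 in the higher group, and for each list described up to 2 members with the largest change and 2 with the highest level, whether or not they pass; 3 genes that it picks are not reported here, though they stay in the tests and lists. Members of a count of 5 or fewer (such as IFIT1, HERC5, MX1, IL18, the SPRR genes and VWF), CYP1B1, ALDH3A1, genes of the overlapping loci and 6 of the held-out receptor targets were named after their values were seen. Cholesterol, ribosomal protein, epidermal lipid and glycolysis lists are given as counts and test without examples by that rule, a limit set after their values were seen, because unpassed members changed sign between scalings.

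The gene test was tried on simulated counts for 19028 genes with the means and library sizes of these samples. Genes were drawn independently with the same dispersion for all, set below the common dispersion of these data, so recovery may be overstated. Counts were drawn on the deposited scale, so recovery at low counts may be overstated further if 4 counts stand for 1 read pair. Of the changed genes that were tested, it recovered 42.9% of those changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4- or 8-fold. There were 12 false calls among 178. In a second simulation of 2000 changed genes, 1.5-fold changes were recovered for 14.3% of tested genes with a mean of up to 50 counts per library and 65.9% of those above 1000. Camera found a simulated list of 30 genes moved 1.4-fold and called 0 of 30 unmoved lists. Because the simulated genes were independent, this does not show how camera behaves for lists of correlated genes. Alternatives were no count filter, a mean FPKM of at least 1, median-of-ratios scaling, quantile normalization with limma, the replicate number as a block, robust empirical Bayes, DESeq2, limma on log2 FPKM with pseudocounts of 0.1 and 0.01, without an intensity trend and on TPM, leaving out each library, fry and an estimated correlation. Limma on log2(FPKM + 1) with the trend, which the design foresaw for a table without counts, was kept as an alternative. Added after seeing the data were total-count scaling, upper-quartile scaling and counts divided by 4. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, data.table (version 1.17.8) and, for plots, matplotlib 3.10.9.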

Results

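Poly(A) RNA was sequenced from HaCaT cells, a spontaneously immortalised human keratinocyte line that grows as a basal-like monolayer. Libraries came from 3 untreated samples and from 3 samples given tumour necrosis factor alpha and interferon gamma at 10 ng/ml for 48 h, a cytokine pair used to provoke an inflammatory state in keratinocytes. The untreated libraries held 64396837, 63629708 and 58144700 counts in total. The treated libraries held 76836303, 75561472 and 77168104 counts. All levels are CPM (counts scaled to a common library total) after TMM scaling, as mean ± SD with n = 3 per group, and each log2 change is treated over untreated. Genes at an FPKM of at least 1 numbered 12285.7 ± 32.0 in the untreated libraries and 11930.3 ± 46.9 in the treated libraries (n = 3 each). That difference of -355.3 genes had a two-sided exact permutation p of 0.1, the smallest that 20 assignments of 6 samples allow. FPKM carry a total-count scale, which lowers treated values relative to TMM scaling, so the difference may come from the scale. Genes with any count overlapped between the groups, at 24783 to 25343 untreated and 25124 to 25235 treated, although the treated totals were larger. Correlations of log2 CPM across genes, which are not independent replicates, were 0.978 to 0.981 within groups and 0.947 to 0.952 between groups.

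The comparison asks how the transcriptome of these keratinocytes differed after 48 h with both cytokines. The treated cells carried far more transcript of interferon and NF-kB target genes, antigen presentation genes and chemokines, and less of the genes for DNA replication and mitosis. GBP1, an interferon-inducible GTPase, rose 107-fold, from 11.3 ± 1.35 to 1208 ± 40.6 CPM. ICAM1, a leukocyte adhesion ligand, rose 42.9-fold, from 27.1 ± 0.725 to 1164 ± 85.0 CPM. PCNA, the sliding clamp of the replication fork, fell from 262 ± 0.465 to 161 ± 5.60 CPM. CYP1A1, a xenobiotic-metabolising cytochrome P450, fell from 89.3 ± 13.8 to 3.64 ± 0.121 CPM.

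Of 19358 genes tested, edgeR's quasi-likelihood test called 7587 (39.2%) at a Benjamini-Hochberg adjusted p under 0.05, 4077 higher and 3510 lower in the treated cells. Rises made up 53.7% of these calls under TMM scaling and 30.1% under scaling by total counts (2521 higher and 5864 lower). That scaling moved the median log2 change of all genes by -0.18. Upper-quartile scaling gave 3403 higher and 4244 lower (44.5% rises), so the balance of rises and falls depended on the scaling. At least 2-fold changes were called for 1945 genes, 1055 higher and 890 lower. Rises made up 54.2% of these against 38.4% under total-count scaling (832 and 1336). The number of at least 2-fold changes was 992 among genes with a mean FPKM of at least 1, 664 by limma on log2(FPKM + 1) without the trend and 1069 by limma on TPM. The smallest change called was 0.14 on the log2 scale and the median size of a called change was 0.56. FPKM ranges of both groups did not overlap for 10464 genes (54.1%), where chance gives 10% if both groups share a scale. FPKM carry the total-count scale, which lowers treated values relative to TMM, so part of the excess may come from scaling. The first principal component of log2 CPM held 58% of the variance and separated the groups.

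**Figure D1:**
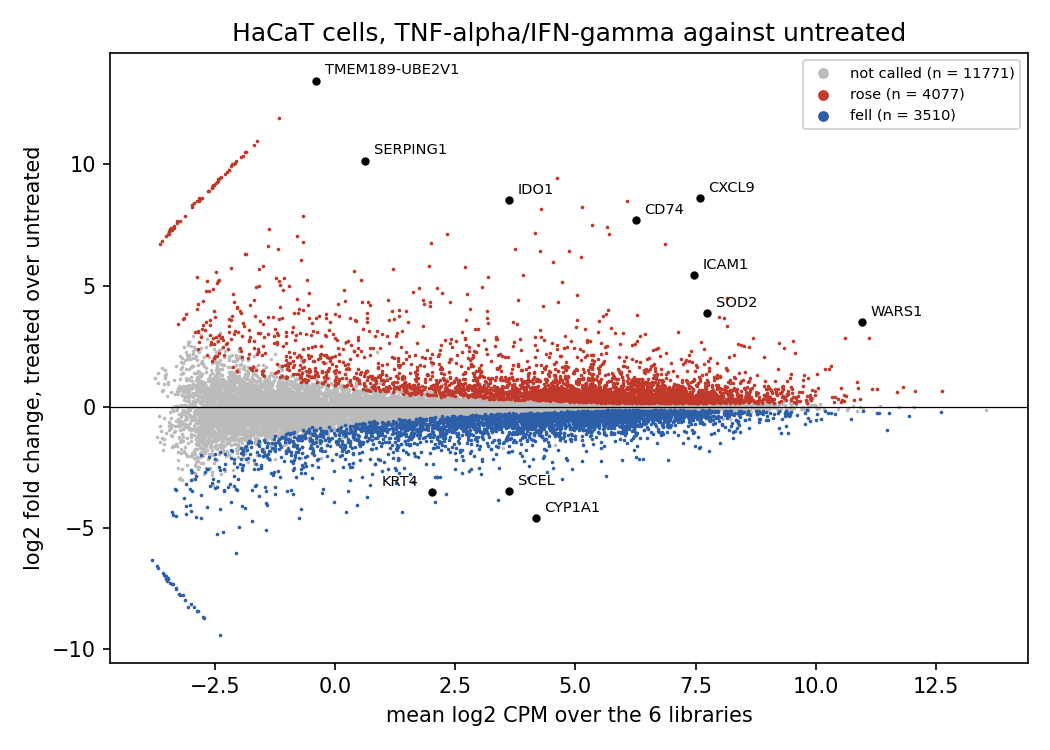
Log2 fold change of treated over untreated libraries against mean log2 CPM over the 6 libraries, one point per tested gene, with 4077 genes that rose in red, 3510 that fell in blue and 11771 not called in grey. The diagonal streaks at the left are genes at 0 counts in 1 group, whose fitted fold changes depend on the prior count and are not measured sizes.

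IRF1, GBP1, NFKBIA and ICAM1, set as a check of the labels, were each higher in all 3 treated libraries than in all 3 untreated ones. IRF1 (ENSG00000125347, GRCh38 chromosome 5, 132481609 to 132490773, minus strand), an interferon-induced transcription factor, rose from 77.7 ± 3.48 to 969 ± 24.6 CPM (log2 change 3.64, SE 0.04, edgeR adjusted p = 2.6e-10). GBP1 (ENSG00000117228) lies on chromosome 1 from 89052319 to 89065230 on the minus strand, among a cluster of similar guanylate-binding protein genes, and its log2 change was 6.74 with SE 0.10 (edgeR adjusted p = 2.35e-10). NFKBIA (ENSG00000100906, chromosome 14, 35401513 to 35404749, minus strand), which encodes the inhibitor IkB-alpha, rose from 55.1 ± 2.29 to 256 ± 12.3 CPM (2.22, SE 0.05, edgeR adjusted p = 4.9e-09). ICAM1 (ENSG00000090339) lies on chromosome 19 from 10271093 to 10285583 on the plus strand, and its log2 change was 5.42 with SE 0.06 (edgeR adjusted p = 2.35e-10).

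Genes with the largest fitted rises were mostly at 0 counts in every untreated library, so their rank depends on the prior count. For those genes the size is a lower bound against a floor of 12 counts per library. Most of these bounds lie below rises measured elsewhere, such as 107-fold for GBP1. SERPING1, the C1 inhibitor of the complement system on chromosome 11 (57597387 to 57614848), had 0, 8 and 0 counts untreated and 3153, 3055 and 4160 counts treated. EBI3, a subunit shared by interleukins 27 and 35, was at least 9.70-fold higher at 1.76 ± 0.592 CPM. HLA-DQA2, an MHC class II chain, was at least 18.0-fold higher at 3.27 ± 0.384 CPM. TEX29 was at least 20-fold higher at 3.63 ± 0.821 CPM. LGALS17A was at least 38.5-fold higher at 7.00 ± 2.42 CPM, and AC092112 at least 10.5-fold higher at 1.9 ± 0.536 CPM. The readthrough gene TMEM189-UBE2V1 on chromosome 20 was at least 112-fold higher at 20.5 ± 4.92 CPM. The readthrough gene TM4SF19-TCTEX1D2 was at least 6.15-fold higher at 1.12 ± 0.225 CPM. Both readthrough models overlap their component genes on the same strand, so their counts are uncertain. The same holds for C20orf141 (at least 6.27-fold higher at 1.14 ± 0.041 CPM), which overlaps AL035460, and for HLA-DQA2, which closely resembles HLA-DQA1. OR2I1P, an olfactory receptor pseudogene, went from 0.947 ± 0.511 to 675 ± 34.3 CPM (log2 change 9.46). It lies opposite UBD, and the strand setting of the counting was not given in the sources used here. The edgeR adjusted p of these 10 genes lay between 4.08e-09 for OR2I1P and 5.81e-05 for TM4SF19-TCTEX1D2.

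Among the largest falls, CYP1A1 (chromosome 15, 74719542 to 74725536, minus strand) fell by 4.61 on the log2 scale with an edgeR adjusted p of 3.73e-09. GDF15, a stress-induced cytokine of the TGF-beta family, fell from 17.2 ± 1.54 to 1.41 ± 0.0611 CPM (log2 change -3.60). SCEL, a precursor protein of the cornified envelope, fell from 41.4 ± 2.82 to 3.70 ± 0.671 CPM (-3.48). KRT4, a keratin of mucosal epithelia, fell from 13.7 ± 2.72 to 1.18 ± 0.102 CPM (-3.53). The aldo-keto reductase gene AKR1B10 fell from 5.61 ± 2.13 to 0.329 ± 0.104 CPM (-4.08). ALPP, placental alkaline phosphatase, fell from 40.5 ± 11.8 to 2.77 ± 0.384 CPM (-3.87). Its near-identical neighbour ALPG, with which reads can be shared, fell from 269, 122 and 266 counts to 19, 10 and 0 counts (-4.62). FGD3, an exchange factor for CDC42, fell from 11.6 ± 0.332 to 0.569 ± 0.154 CPM (-4.34). CAVIN2, a coat protein of caveolae, fell from 16.6 ± 2.17 to 1.08 ± 0.281 CPM (-3.94), and the calpain protease gene CAPN8 from 14 ± 2.68 to 1.25 ± 0.254 CPM (-3.49).

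**Figure D2:**
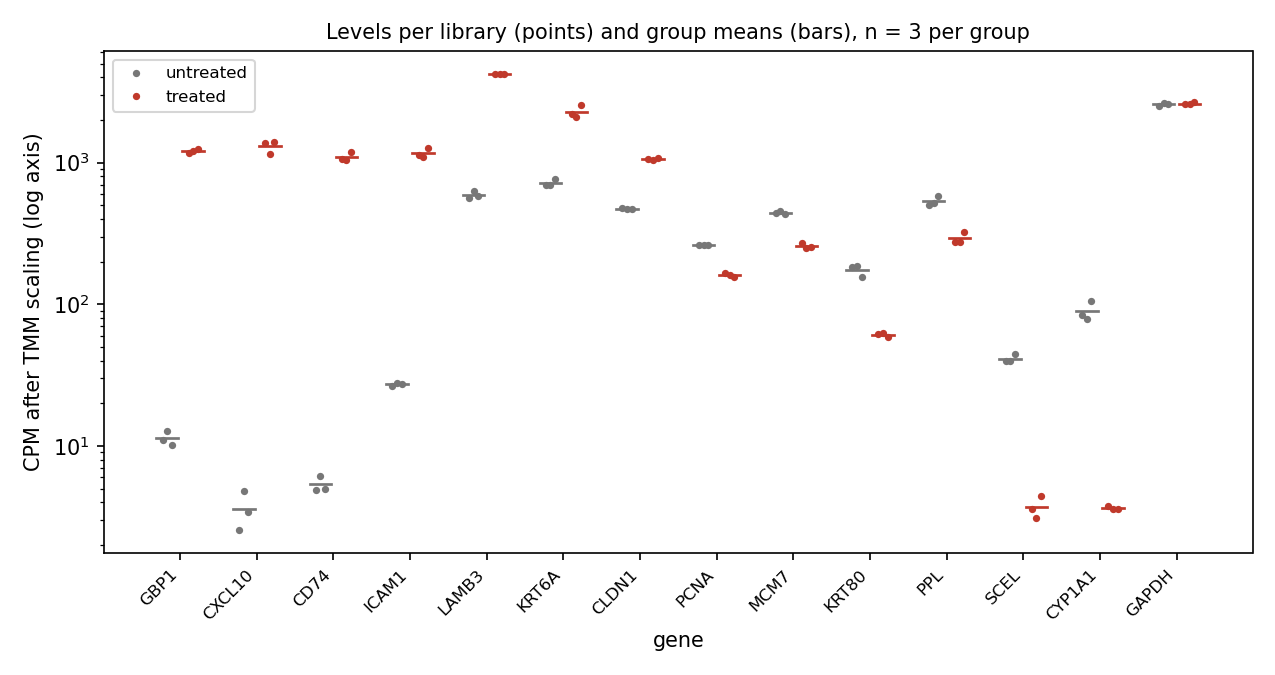
CPM after TMM scaling on a log axis for 14 genes in the 3 untreated (grey) and 3 treated (red) libraries, with points for libraries and bars for group means. GBP1, CXCL10, CD74 and ICAM1 reached 1103 to 1304 CPM in the treated cells, whereas GAPDH was at 2583 CPM untreated and 2610 CPM treated (log2 change -0.16 under total-count scaling).

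Interferon response genes rose nearly throughout. All 23 tested genes of interferon gamma signalling and the GBP family rose (camera adjusted p = 3.56e-23), also when adjusted over the list alone, with a median log2 change of 2.84. They took 0.163% of all counts in the untreated libraries and 1.27% in the treated ones. WARS1, the tryptophanyl-tRNA synthetase, rose from 600 ± 4.10 to 6685 ± 609 CPM, and IDO1, which degrades tryptophan, rose 367-fold from 0.647 ± 0.260 CPM. GBP5 rose from 1.16 ± 0.353 to 330 ± 47.4 CPM, and UBD, a ubiquitin-like modifier, from 3.03 ± 0.560 to 557 ± 170 CPM. Of 38 antiviral interferon-stimulated genes, 35 rose and 2 fell, with equal counts when adjusted over the list alone (median 2.19, camera adjusted p = 7.06e-24). OAS3, a sensor of double-stranded RNA, rose from 135 ± 13.7 to 817 ± 67.3 CPM. The ubiquitin ligase gene DTX3L rose from 240 ± 7.66 to 986 ± 38.8 CPM, XAF1 by 4.92 and BST2, which tethers budding virions, by 4.33 on the log2 scale. IFIT1, a binder of foreign RNA, fell from 106 ± 5.92 to 65.3 ± 1.71 CPM (log2 change -0.70, edgeR adjusted p = 1.02e-05). HERC5, the ISG15 ligase, fell from 1.46 ± 0.259 to 0.649 ± 0.0484 CPM (-1.16, edgeR adjusted p = 0.00672). MX1, a dynamin-like antiviral GTPase, had a log2 change of -0.22 that missed the threshold (edgeR adjusted p = 0.583) and was 0.00023 without treated replicate 1.

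Genes of both antigen presentation lists were called higher throughout under TMM scaling. Each of 20 MHC class I pathway genes was called higher (median 2.15, camera adjusted p = 1.04e-21), and the same number when adjusted over the list alone. HLA-E rose from 154 ± 3.37 to 874 ± 41.3 CPM. The peptide transporter gene TAP1 rose from 59.5 ± 3.90 to 1349 ± 64.2 CPM, and the immunoproteasome subunit gene PSMB9 from 13 ± 0.108 to 175 ± 33.9 CPM. All 15 MHC class II pathway genes rose as well (median 5.45, camera adjusted p = 4.74e-17), again also when adjusted over the list alone. Their share of counts went from 0.00973% to 0.211%. CD74, the invariant chain, rose from 5.35 ± 0.723 to 1103 ± 78.2 CPM, HLA-DRA from 2.08 ± 0.436 to 179 ± 15.6 CPM. The lysosomal protease gene CTSS rose from 3.17 ± 0.262 to 270 ± 19.3 CPM, and HLA-DPB1 from 4, 2 and 0 counts to 595, 463 and 577 counts. Reads of the MHC genes can be shared between similar members, so the level of a single HLA gene is uncertain. Under total-count scaling, 19 class I genes and 14 class II genes rose.

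NF-kB targets and secreted signals rose with them. Among 26 NF-kB feedback and target genes, 25 rose and none fell, also when adjusted over the list alone (median 1.70, camera adjusted p = 2.26e-20). SOD2, the mitochondrial superoxide dismutase, rose from 56.3 ± 4.56 to 824 ± 55.2 CPM, and IER3 by 0.35 on the log2 scale. BCL2A1, an anti-apoptotic BCL2 relative, rose from 0, 8 and 0 counts to 257, 329 and 250 counts, and LTB, lymphotoxin beta, was at least 5.96-fold higher from 0 counts. Chemokines were called higher for 15 of 17 genes and lower for none, also when adjusted over the list alone (median 3.02, or 2.88 with CXCL5 at its lower bound, camera adjusted p = 7.17e-12). CXCL9, a ligand of CXCR3, a chemokine receptor of T cells, rose from 9.93 ± 2.92 to 3862 ± 419 CPM. CXCL10, which binds the same receptor, rose from 3.60 ± 1.14 to 1304 ± 137 CPM. CXCL5, a neutrophil attractant, was at least 5.39-fold higher from 0 counts. Epithelial cytokines and their receptors gave 24 rises and 2 falls among 33 genes, with equal counts when adjusted over the list alone (median 1.31, or 1.08 with IL36B at its lower bound, camera adjusted p = 2.38e-10). IL32 rose from 4.40 ± 0.815 to 618 ± 55.2 CPM, IL1A from 124 ± 13.2 to 222 ± 11.4 CPM, and IL36B was at least 1.64-fold higher from 0 counts. IL18 fell from 38.2 ± 5.30 to 27.3 ± 0.971 CPM (log2 change -0.48). IL20RA, a receptor chain of the interleukin 20 family, fell from 4.87 ± 0.602 to 0.775 ± 0.153 CPM (-2.65).

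Innate effectors, adhesion ligands and death pathway genes were mostly higher. Complement and acute phase genes gave 16 rises and 1 fall among 21, or 2 falls when adjusted over the list alone (median 2.05, camera adjusted p = 3.99e-11). C1S, a protease of the classical pathway, rose from 3.87 ± 0.772 to 659 ± 20.3 CPM and the urokinase gene PLAU from 246 ± 15.5 to 1504 ± 21.7 CPM. LCN2, an iron-sequestering lipocalin, fell from 213 ± 4.11 to 144 ± 4.52 CPM. Antimicrobial and S100 genes gave 7 rises and 1 fall, the same LCN2, among 10, or 8 rises when adjusted over the list alone (camera adjusted p = 0.000489; adjusted p = 0.184 with an estimated correlation). PI3, the elastase inhibitor elafin, rose by 3.96, RNASE7 by 2.20, S100A11 by 1.09 and S100A16 by 0.79 on the log2 scale. Immune checkpoint and adhesion ligand genes gave 15 rises and 1 fall among 18, with equal counts when adjusted over the list alone (median 1.12, camera adjusted p = 3.56e-09). ULBP1, a ligand of the natural killer receptor NKG2D, fell from 4.5 ± 0.960 to 1.67 ± 0.210 CPM. Cell death and pyroptosis genes gave 32 rises and 1 fall among 38, or 33 rises when adjusted over the list alone (median 0.74, or 0.69 with ZBP1 at its lower bound, camera adjusted p = 7.77e-15). NLRP3, an inflammasome sensor, rose from 0.505 ± 0.0253 to 28.1 ± 1.33 CPM and MCL1 from 565 ± 20.9 to 942 ± 38.2 CPM. ZBP1, a sensor of Z-form nucleic acid, was at least 1.4-fold higher from 0 counts. BCL2L1 had a log2 change of 0.18 (edgeR adjusted p = 0.0154) and did not pass without untreated replicate 1 (0.0914) or untreated replicate 3 (0.0698). Its log2 change was -0.0030 under total-count scaling and -0.041 after quantile normalization. BCL2 was lower at -0.48 (edgeR adjusted p = 0.0481). It missed the threshold in 5 of the 6 fits without 1 library, all but that without treated replicate 1 (0.0719 to 0.132).

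**Figure D3:**
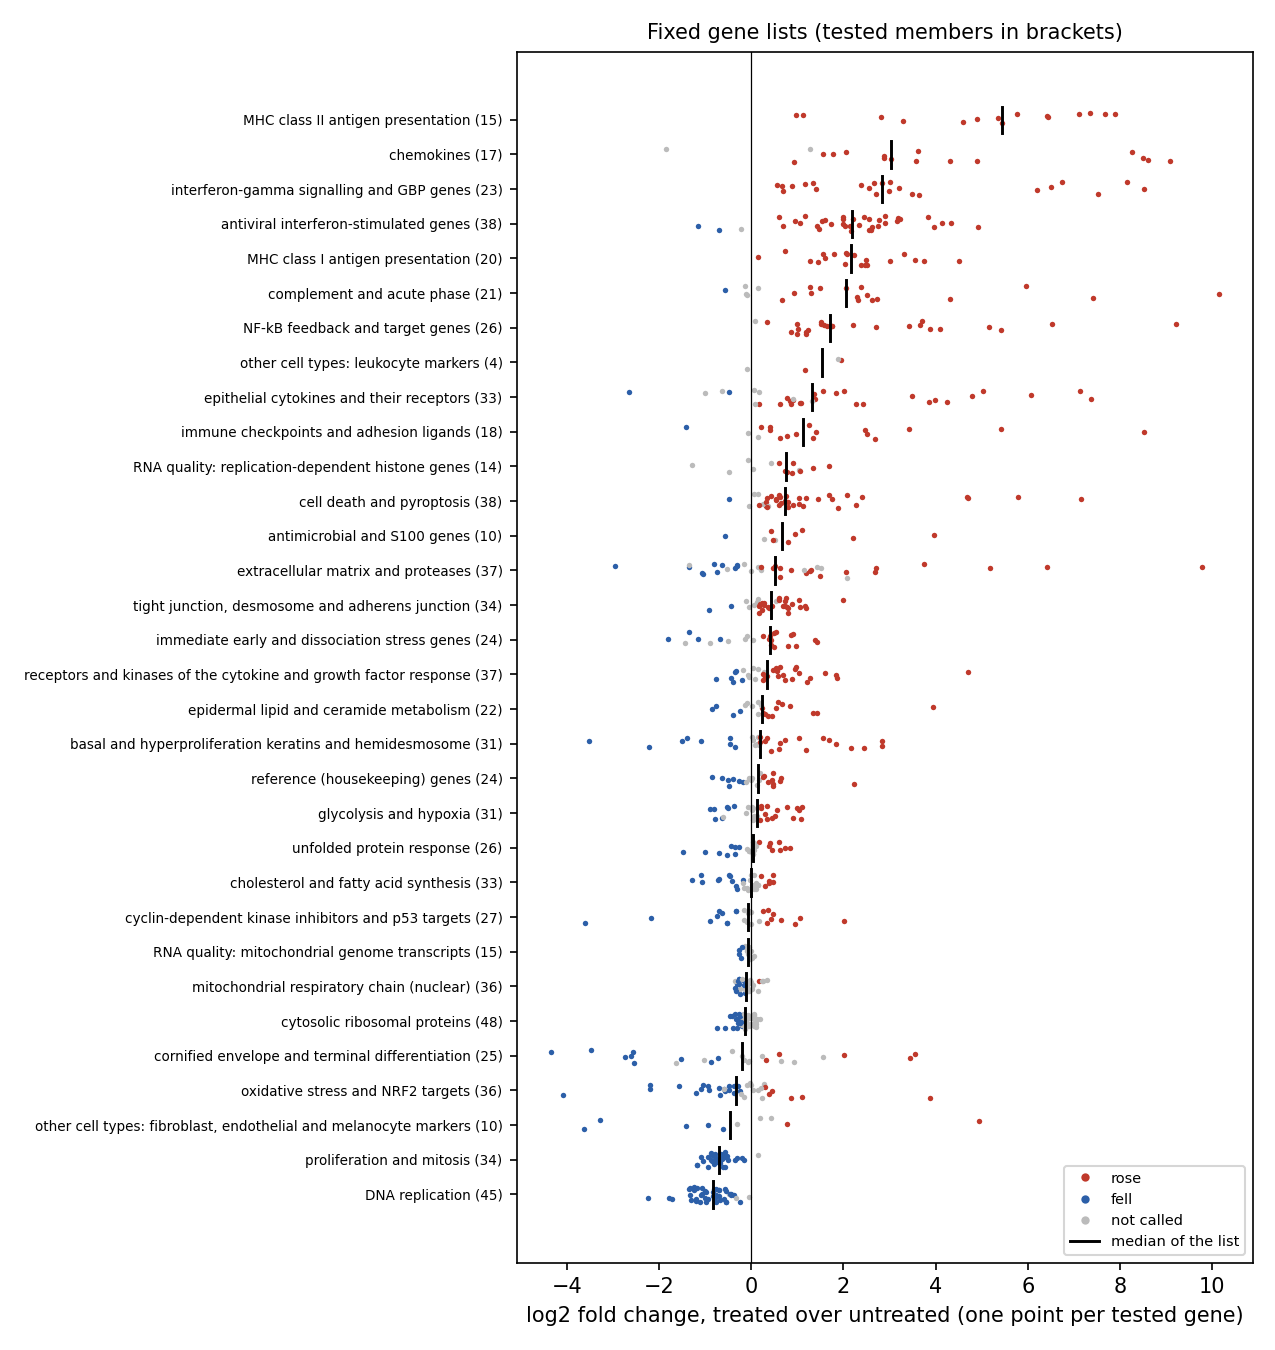
Log2 fold change of every tested member of the 32 fixed gene lists, one point per gene, red for genes that rose, blue for genes that fell and grey for genes not called, with a black bar at each list's median. MHC class II genes lie farthest to the right with a median of 5.45 and DNA replication genes farthest to the left with a median of -0.82; fitted changes of members at 0 counts in the untreated libraries depend on the prior count.

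Keratinocyte structural genes moved in both directions. Cornified envelope and terminal differentiation genes gave 5 rises and 9 falls among 25, or 10 falls when adjusted over the list alone (median -0.19, camera adjusted p = 0.0209; adjusted p = 0.303 with an estimated correlation). This call also missed the threshold without untreated replicate 1 (0.0594) and untreated replicate 3 (0.110) and under total-count scaling (4 rises, 12 falls, 0.104). Its adjusted p lay between 0.000499 and 0.303 over all alternatives. HRNR, the filaggrin-like protein hornerin, fell from 5.08 ± 0.385 to 0.246 ± 0.0734 CPM and KRT80 from 175 ± 17.5 to 60.8 ± 1.74 CPM. PPL, the desmosomal plakin periplakin, fell from 534 ± 44.6 to 292 ± 27.9 CPM. The 5 rises were the envelope precursors SPRR1A (4, 2 and 4 counts to 49, 34 and 50 counts), SPRR1B (log2 change 3.45) and SPRR2E (2.01) and the epithelial transcription factors OVOL1 (0.59) and GRHL3 (0.31). GRHL3 did not pass without untreated replicate 1 (edgeR adjusted p = 0.0637), without untreated replicate 2 (0.0558) or under total-count scaling (0.190).

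Basal and hyperproliferation keratins with hemidesmosome genes gave 17 rises and 8 falls among 31, or 18 rises when adjusted over the list alone (median 0.20, camera adjusted p = 0.00106; adjusted p = 0.396 with an estimated correlation). Their share of counts went from 1.47% to 2.72%. Of these changes, 9 rises and 5 falls were at least 2-fold, and the largest was the fall of KRT4 (log2 change -3.53). LAMB3, a chain of the basement membrane laminin 332, rose from 589 ± 34.2 to 4197 ± 4.90 CPM. KRT6A, a keratin of activated epidermis, rose from 716 ± 39.6 to 2288 ± 235 CPM, with KRT6B and KRT6C as near-identical copies. Under total-count scaling, 14 of these genes rose, 8 fell and the median was 0.02. Tight junction, desmosome and adherens junction genes gave 26 rises and 2 falls among 34, with equal counts when adjusted over the list alone (median 0.42, camera adjusted p = 4.19e-09; adjusted p = 0.14 with an estimated correlation). Under total-count scaling 18 rose and 4 fell. CLDN1, a claudin that seals tight junctions, rose from 473 ± 7.89 to 1057 ± 11.7 CPM and CGN, cingulin, from 26.8 ± 1.70 to 61.5 ± 2.07 CPM. The connexin gene GJB2 rose from 1.99 ± 0.366 to 7.93 ± 2.85 CPM, and JUP, plakoglobin, by 0.46 on the log2 scale (0.14 after quantile normalization, adjusted p = 0.0996). TJP3 (log2 change -0.93) and PKP2, a desmosomal plakophilin (-0.44), fell.

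Epidermal lipid and ceramide genes gave 12 rises and 4 falls among 22, with equal counts when adjusted over the list alone (camera adjusted p = 0.0194; adjusted p = 0.128 with an estimated correlation). The call missed the threshold without treated replicate 3 (0.0526; 0.000523 to 0.128 over all alternatives). Their median of 0.24 was 0.06 under total-count scaling, where 8 rose and 5 fell. The 4 falls were the ceramide synthase gene CERS6 (log2 change -0.77), the serine palmitoyltransferase subunit genes SPTLC2 (-0.25) and SPTLC3 (-0.86), and the acid ceramidase gene ASAH1 (-0.39). SPTLC2 did not pass without treated replicate 2 (edgeR adjusted p = 0.06). Extracellular matrix and protease genes gave 17 rises and 10 falls among 37, or 18 rises when adjusted over the list alone (median 0.51, camera adjusted p = 0.0232; adjusted p = 0.260 with an estimated correlation). MMP9, a gelatinase, was at least 8.75-fold higher from 0 counts, and SERPINB2, an inhibitor of plasminogen activators, rose from 288 ± 3.29 to 1887 ± 72.6 CPM. THBS1, a matricellular thrombospondin, fell from 1175 ± 81.8 to 942 ± 28.3 CPM.

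Genes of the mitosis and DNA replication lists were lower nearly throughout. Of 34 proliferation and mitosis genes, 33 fell and none rose, also when adjusted over the list alone (median -0.71, camera adjusted p = 1.08e-17). KIF20A, a kinesin of the central spindle, fell from 75.2 ± 8.78 to 32.9 ± 0.618 CPM. The proliferation-linked transcription factor gene MYBL2 fell from 116 ± 3.24 to 51.2 ± 4.68 CPM, and TPX2, a spindle assembly factor, from 453 ± 2.28 to 352 ± 9.84 CPM. The remaining member, UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, was at 82.5 ± 4.53 and 91.6 ± 7.88 CPM (log2 change 0.15, edgeR adjusted p = 0.13; -0.027 under total-count scaling). Among 45 DNA replication genes, 42 fell and none rose, also when adjusted over the list alone (median -0.82, camera adjusted p = 1.2e-23). Their share of counts went from 0.460% to 0.235%. E2F2 fell from 18.3 ± 1.26 to 3.83 ± 0.822 CPM, and LIG1, which seals nicks between replication fragments, from 46.7 ± 6.68 to 13.5 ± 1.49 CPM. The replicative helicase subunit gene MCM7 fell from 444 ± 9.89 to 259 ± 11.8 CPM. Cyclin-dependent kinase inhibitor and p53 target genes gave 9 rises and 10 falls among 27, with equal counts when adjusted over the list alone. The list was not called (camera adjusted p = 0.426; 7 rises and 14 falls under total-count scaling). CDKN2C, an inhibitor of CDK4 and CDK6, fell by 2.17 on the log2 scale, whereas CCND1, cyclin D1, rose from 683 ± 2.50 to 923 ± 23.6 CPM. MYC was at 646 ± 30.6 and 575 ± 61.3 CPM (log2 change -0.17, edgeR adjusted p = 0.114). It passed the test without treated replicate 3 (0.0142), with the replicate block (0.0267) and under total-count scaling (-0.35, 0.00294).

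Metabolic and stress genes showed smaller or mixed changes. Oxidative stress and NRF2 target genes gave 6 rises and 19 falls among 36, or 8 and 20 when adjusted over the list alone (median -0.33, camera adjusted p = 0.0021; adjusted p = 0.454 with an estimated correlation). The ferritin subunit genes FTL and FTH1 fell from 657 ± 31.2 to 468 ± 17.9 CPM and from 4512 ± 186 to 3461 ± 348 CPM. Unfolded protein response genes gave 8 rises and 8 falls among 26, with equal counts when adjusted over the list alone. Their median was 0.03, their mean -0.03 and the camera direction downward (adjusted p = 0.875). Under total-count scaling 5 rose, 14 fell and the median was -0.15. TRIB3, a pseudokinase induced by the integrated stress response, fell from 435 ± 13.5 to 155 ± 19.7 CPM, and CHAC1, a glutathione-degrading enzyme, from 11.5 ± 1.79 to 5.74 ± 1.15 CPM. In contrast, PPP1R15A, a phosphatase subunit that acts on eIF2-alpha, rose from 383 ± 26.3 to 690 ± 50.5 CPM. HSPA5, the chaperone BiP, had a log2 change of -0.10 (edgeR adjusted p = 0.179; -0.28 and 0.00164 under total-count scaling).

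Nuclear genes of the mitochondrial respiratory chain gave 1 rise and 13 falls among 36, or 2 and 14 when adjusted over the list alone (median -0.11, camera adjusted p = 0.0131; adjusted p = 0.567 with an estimated correlation). This call did not hold without treated replicate 3 (0.111; 0.000139 to 0.567 over all alternatives). Under total-count scaling 20 fell and none rose, and under upper-quartile scaling 17 fell and none rose. COX7B fell from 23.9 ± 1.63 to 18.7 ± 0.208 CPM, while NDUFB3 was at 6.11 ± 0.559 and 7.79 ± 1.34 CPM (log2 change 0.35, edgeR adjusted p = 0.108, and 0.0280 without treated replicate 3). CYC1 (-0.15) and ATP5F1B (-0.16) passed with all libraries and missed the threshold in 5 and 4 of the 6 fits without 1 library (edgeR adjusted p = 0.0512 to 0.105 and 0.0548 to 0.0831). CYC1 kept its call only without treated replicate 1, and ATP5F1B without treated replicate 1 or untreated replicate 2. The single rise, NDUFA9 (0.17), was not called in the 4 fits without any of untreated replicates 1, 2 and 3 or treated replicate 2 (0.0638 to 0.107), and was -0.0078 under total-count scaling. Cytosolic ribosomal protein genes gave no rise and 18 falls among 48, also when adjusted over the list alone (median -0.14, camera adjusted p = 0.000454; adjusted p = 0.528 with an estimated correlation). Under total-count scaling 34 fell. Cholesterol and fatty acid synthesis genes gave 6 rises and 11 falls among 33, or 12 falls when adjusted over the list alone. This list was not called (camera adjusted p = 0.226; 4 rises, 17 falls and 0.0235 under total-count scaling, 0.00628 to 0.326 over all alternatives). Glycolysis and hypoxia genes gave 15 rises and 7 falls among 31, or 17 and 8 when adjusted over the list alone, and were not called (camera adjusted p = 0.118). Their median was 0.13. Under total-count scaling 9 rose, 10 fell and the median was -0.05.

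Receptors and kinases of the cytokine and growth factor response gave 23 rises and 6 falls among 37, or 24 rises when adjusted over the list alone (median 0.35, camera adjusted p = 1.8e-05; adjusted p = 0.154 with an estimated correlation). Under total-count scaling 17 rose and 9 fell. TNFRSF1B, a receptor for tumour necrosis factor, rose from 0.925 ± 0.410 to 24.4 ± 3.62 CPM and the phosphatase gene DUSP5 from 40 ± 3.67 to 146 ± 11.5 CPM. AREG, an EGFR ligand, fell from 211 ± 10.0 to 159 ± 12 CPM. EGFR was at 1658 ± 19.6 and 1611 ± 137 CPM (log2 change -0.04, edgeR adjusted p = 0.655). Its change was 0.024 without treated replicate 1 and -0.22 under total-count scaling (0.0115). Immediate early and dissociation stress genes gave 14 rises and 4 falls among 24, or 5 falls when adjusted over the list alone (median 0.39, mean 0.07, camera adjusted p = 0.0111; adjusted p = 0.215 with an estimated correlation). The heat shock protein genes HSPA8 and HSPA1A, the latter with a near-identical copy, rose by 0.49 and 0.40 on the log2 scale (0.11 and 0.07 after quantile normalization, adjusted p = 0.0592 and 0.283). EGR1 fell from 145 ± 33.9 to 41.7 ± 18.6 CPM, and the other falls were FOS (log2 change -1.36), FOSB (-0.68) and the metallothionein gene MT1X (-1.15). EGR3 was near the floor at 0.290 ± 0.0847 and 0.106 ± 0.0551 CPM and did not pass (edgeR adjusted p = 0.109).

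Reference genes were not steady: 10 of 24 rose and 7 fell, or 11 and 7 when adjusted over the list alone, and the list was not called (median 0.14, camera adjusted p = 0.226; 8 rises, 10 falls and a median of -0.04 under total-count scaling). B2M, the MHC class I light chain, rose from 352 ± 6.10 to 1646 ± 137 CPM and ACTB, beta-actin, from 3430 ± 154 to 5367 ± 297 CPM. GAPDH had a log2 change of 0.02 (edgeR adjusted p = 0.825), which was -0.16 under total-count scaling (0.00891), -0.051 under upper-quartile scaling and -0.016 without untreated replicate 1.

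Markers of other cell types were scarce. Among leukocyte markers 4 genes could be tested, too few for a set test, and 2 rose, also when adjusted over the list alone: CSF1R, from 3.78 ± 0.205 to 8.5 ± 0.189 CPM, and the lysosomal glycoprotein gene CD68, from 20.7 ± 2.38 to 79.6 ± 3.63 CPM. ITGAM was at 0.149 ± 0.209 and 0.549 ± 0.326 CPM and not called (edgeR adjusted p = 0.177, and 0.0207 without untreated replicate 3). Fibroblast, endothelial and melanocyte markers gave 2 rises and 5 falls among 10, with equal counts when adjusted over the list alone, and were not called (median -0.46, camera adjusted p = 0.335). PDGFRA, a growth factor receptor of mesenchymal cells, rose from 8, 2 and 0 counts to 133, 114 and 98 counts, and ACTA2 from 2.12 ± 0.308 to 3.63 ± 0.602 CPM. That last call was lost without untreated replicate 1 (edgeR adjusted p = 0.0553) or untreated replicate 2 (0.0523). CDH5, VE-cadherin, fell from 1.79 ± 0.578 to 0.143 ± 0.0545 CPM and MITF from 8.22 ± 1.22 to 5.40 ± 0.169 CPM. VWF (log2 change -3.30), PMEL (-0.94) and TYRP1 (-1.41) passed narrowly and missed the threshold in 5, 4 and 6 of the 6 fits without 1 library (edgeR adjusted p = 0.0515 to 0.101, 0.0515 to 0.107 and 0.0576 to 0.118). PMEL kept its call without untreated replicate 1 or treated replicate 2. VWF, with 0, 0 and 30 counts in the treated libraries, kept its call without treated replicate 3, where all treated counts are 0 and the fitted change of -9.57 depends on the prior count. Its change lay between -3.57 and -2.71 in the other 5 of these fits.

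Transcripts of the mitochondrial genome took 3.95% of counts in the untreated and 3.22% in the treated libraries. Of 15 genes 4 fell and none rose, or 3 falls when adjusted over the list alone. The list was not called (median -0.08, camera adjusted p = 0.0913). It was called without untreated replicate 1 (0.0225), untreated replicate 2 (0.0347) or treated replicate 3 (0.0109). It was also called with the replicate number as a block (0.0387), after quantile normalization (1.35e-05), under upper-quartile scaling (0.0257) and under total-count scaling (12 falls, 0.00395), its adjusted p lying at 1.35e-05 to 0.578 over all alternatives. MT-CO2 fell from 2808 ± 128 to 2331 ± 176 CPM and MT-CO3 from 2745 ± 118 to 2275 ± 148 CPM, and both encode subunits of cytochrome c oxidase. MT-ND3 (log2 change -0.22) and MT-ATP6 (-0.20) passed with all libraries and missed the threshold in 4 of the 6 fits without 1 library (edgeR adjusted p = 0.0520 to 0.103 and 0.0618 to 0.108). These were the fits without untreated replicates 1 and 3 and treated replicates 2 and 3 for MT-ND3, and for MT-ATP6 those without untreated replicates 1 and 3 and treated replicates 1 and 2. MT-CO1 was at 12532 ± 287 and 11361 ± 909 CPM (edgeR adjusted p = 0.0862, 0.0222 without treated replicate 3 and 0.0332 with the replicate block), and MT-ATP8 at 876 ± 71.1 and 827 ± 38.6 CPM (0.37, and 0.00766 under total-count scaling). Replication-dependent histone genes gave 8 rises and no fall among 14, also when adjusted over the list alone (median 0.76, camera adjusted p = 0.00123; adjusted p = 0.303 with an estimated correlation). Under total-count scaling 8 rose and 1 fell. H2BC5 rose from 32.1 ± 2.86 to 81.2 ± 9.94 CPM, H2BC12 from 49.1 ± 6.82 to 81.4 ± 8.80 CPM and H2BC8 from 4.06 ± 0.499 to 13 ± 1.37 CPM. Similar members of this family can share reads.

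Of the 31 lists tested, camera with a preset correlation of 0.01 called 24, 18 higher and 6 lower. With the correlation estimated from the residuals 12 calls held: interferon gamma signalling, antiviral genes, both MHC lists, NF-kB targets, chemokines, epithelial cytokines, complement, checkpoints, cell death, proliferation and DNA replication, with adjusted p between 0.0254 and 0.0469. That form also tests with fewer degrees of freedom, so a lost call need not reflect correlated genes. The epidermal lipid list was lost there with an estimated correlation of -0.0002. The rotation test fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, called 26 lists, and its mixed form, which asks whether they change in either direction, called 30.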

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

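Total-count scaling, upper-quartile scaling and counts divided by 4 were chosen after the data were seen, and the other alternatives were planned. The number of genes called lay between 6319 (without untreated replicate 1) and 8385 (total-count scaling) against 7587, with 7986 by DESeq2. Leaving out 1 library gave 6319 to 7461 genes, 1830 to 2022 genes changed at least 2-fold and 23 to 25 lists. At least 2-fold changes, 1945 with all libraries, numbered 992 with a mean FPKM of at least 1 and 1069 with TPM. Limma with the trend gave 1346 on log2(FPKM + 0.01), 1223 on log2(FPKM + 0.1) and 666 on log2(FPKM + 1), the last 664 without the trend. The FPKM fits with the trend shared genes, scale and test, so among them a larger pseudocount lowered the number. All of these fits tested fewer genes (12197 with a mean FPKM of at least 1, 14092 in the others). The FPKM and TPM fits also changed scale and test. What the gene filter, the scale and the test each contributed was not tested. Estimated correlations left 12 of 24 lists and 0 of 302 annotation terms (lowest adjusted p 0.315, where 302 terms had passed camera with the preset correlation). This form of camera also tests with fewer degrees of freedom, so a lost call does not show that correlation between genes was the reason. The term for type I interferon signalling had an estimated correlation of -0.0020, below the preset 0.01, and was still lost (camera adjusted p = 0.315). Total-count scaling kept 6031 of the 7587 genes called with the same sign, gave 104 the other sign and called 0 in the opposite direction; quantile normalization called 6 in the opposite direction. The FPKM-based fits moved the median log2 change of all genes by -0.10 to -0.14.

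Of 153 named genes, 126 kept their call and sign under every alternative in which they had a value, and 6 changed sign. GAPDH changed from 0.02 to -0.023 with a mean FPKM of at least 1, -0.35 after quantile normalization, -0.15 with each FPKM pseudocount (0.1, 0.01, and 1 with or without the trend), -0.13 with TPM, -0.16 with total counts, -0.051 with the upper quartile and -0.0019 with counts divided by 4, and lay between -0.016 and 0.024 without 1 library. UBE2C changed to -0.020 in the FPKM fits with pseudocounts 0.1, 0.01 and 1 (with or without the trend) and to -0.027 with total counts, BCL2L1 to -0.041 after quantile normalization and -0.0030 with total counts, and NDUFA9 to -0.0078 with total counts. Without 1 library, EGFR lay between -0.098 and 0.024 and MX1 between -0.43 and 0.00023. Total-count and upper-quartile scaling lower every change by a common amount, and FPKM carry the total-count scale. In the FPKM fits UBE2C (-0.020) and GAPDH (-0.15) lay close to their values with total counts (-0.027 and -0.16), so these sign changes go with that scale. The cause of the other sign changes was not tested.

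Of 31 lists, 12 kept their call and direction under every alternative. The unfolded protein response list turned upward with no count filter (adjusted p 0.944), with fry (0.470), and without treated replicates 1 and 2, its adjusted p lying between 0.564 and 0.998 without 1 library. After quantile normalization glycolysis (0.564) and reference genes (0.378) turned downward. Cornified envelope, epidermal lipid and extracellular matrix lists missed the threshold most often, in 12, 9 and 8 of 22 alternatives. No cause was tested for these.

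The labels do not describe equal replicate numbers as pairs (correlations of deviations 0.0157 to 0.0481 for equal numbers). The replicate block called 7611 genes, 1888 of them changed at least 2-fold, 25 lists and 313 terms, and kept 7262 of the 7587 calls. It also called MYC (0.0267), ITGAM (0.0473), MT-CO1 (0.0332) and the mitochondrial genome list (0.0387), and no longer called CYC1 (0.0501), BCL2 (0.0646) and TYRP1 (0.0765). In these deviations each library correlated best with its own number across groups, which did not hold for the log2 CPM themselves. On the second principal component of log2 CPM (11.3% of the variance) untreated and treated replicate 3 lay at -48.4 and -27.7. The other libraries lay at 9.57 to 34.3, so a batch shared by replicate number stays open. Genes detected fell by 624.7 at an FPKM of at least 0.1 and by 375 at 5, both on the total-count scale that lowers treated values. Depth limits low genes: 1.5-fold changes were recovered for 14.3% of tested simulated genes with a mean of up to 50 counts per library, against 65.9% above 1000.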

Other observations

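Chosen after the results were seen were the scaling test of CYP1A1, CYP1B1 and ALDH3A1, the near-floor limits on the histone and overlap tests, the merging of shared loci and the tests of single loci; the bounds of the other tests here were written before their results. Among 1700 annotation terms, 302 passed camera with the preset correlation, 161 higher and 141 lower, and 0 passed with an estimated correlation (lowest adjusted p 0.315), so each term below is lost there. Some members also belong to the fixed lists. Proteasome subunit genes were higher in the treated cells, with 31 of 42 called higher and 0 lower, 25 of the 36 outside the lists among them (whole term: camera adjusted p = 1.26e-09; adjusted p = 0.517 with an estimated correlation). Phagosome genes gave 69 rises and 11 falls among 117, or 41 and 9 among the 83 outside the fixed lists (whole term: camera adjusted p = 8.46e-11; adjusted p = 0.315 with an estimated correlation). NOD-like receptor signalling genes gave 91 rises and 14 falls among 136, or 40 and 11 among the 77 outside (whole term: camera adjusted p = 2.66e-13; adjusted p = 0.315 with an estimated correlation).

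Lower terms included DNA repair, ciliary and catabolic genes. The Fanconi anemia pathway, which repairs crosslinks between strands, gave 2 rises and 29 falls among 54 genes, 4 of them in the DNA replication list (camera adjusted p = 3.23e-05; adjusted p = 0.365 with an estimated correlation). Mismatch repair gave 3 rises and 18 falls among 23, of which 10 are in the DNA replication list; the other 13 gave 3 rises and 9 falls (whole term: camera adjusted p = 4.04e-06; adjusted p = 0.365 with an estimated correlation). Genes of the ciliary transition zone, the gate at the base of the cilium, gave 2 rises and 17 falls among 29 (camera adjusted p = 4.66e-05; adjusted p = 0.315 with an estimated correlation). Fatty acid beta-oxidation gave 0 rises and 19 falls among 40 genes (camera adjusted p = 0.000814; adjusted p = 0.482 with an estimated correlation). Degradation of branched-chain amino acids gave 4 rises and 19 falls among 44 (0.00143; adjusted p = 0.505 with an estimated correlation). Steroid hormone biosynthesis, a set that holds CYP1A1, gave 1 rise and 16 falls among 30 (0.000282; adjusted p = 0.428 with an estimated correlation).

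CYP1A1 (log2 change -4.61), CYP1B1 (76.7 ± 22.7 to 9.74 ± 3.32 CPM, -2.98) and ALDH3A1 (135 ± 29.3 to 18.4 ± 1.78 CPM, -2.88), known targets of the aryl hydrocarbon receptor, fell together. Scaling between libraries is argued against as the source by size alone. The 4 scalings moved the median log2 change of all genes by -0.18 at most, while the highest change of these genes was -2.88 (total-count scaling included). With shifts of that size the scaling test could not have come out otherwise. A candidate explanation is lower activity of the receptor, which would lower other targets too. Under TMM scaling, 10 targets held out of the pattern had a median log2 change of -0.38, with a 95% bootstrap interval of -0.95 to 0.15. That median was short of the -0.5 set for the explanation, as it was with median-of-ratios (-0.38) and upper-quartile scaling (-0.45). Only total-count scaling took it past that bound (-0.56). Of these 10, UGT1A6, which shares exons with other UGT1A genes (-2.08), SLC7A5 (-0.96), NQO1 (-0.95), EREG (-0.76) and ABCG2 (-0.41) fell, SERPINB2 (2.71) and TIPARP (0.22) rose, and 3 were not called; TIPARP was lost without untreated replicate 2 (0.0704) or treated replicate 2 (0.0634) and under total-count scaling (0.596; adjusted p 0.00191 to 0.596 over all alternatives). Lower receptor activity and a fall of these genes by another route under the cytokines cannot be told apart. The held-out targets move in both directions, their median passes the bound only under total-count scaling, and several respond to other pathways as well.

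Replication-dependent histone genes were higher (median 0.76, 95% bootstrap interval 0.18 to 0.98 over genes taken as independent) while DNA replication genes were lower. With 8 of 14 called, the list passed camera with the preset correlation but was lost with an estimated one (adjusted p = 0.303). Weaker poly(A) selection in the treated libraries may raise transcripts that lack a poly(A) tail, and would then raise other such RNAs: 54 tested small nucleolar, small nuclear and similar RNAs had a median log2 change of -0.068 (-0.34 to 0.09), with 0 called higher and 0 lower by edgeR. This met the bound written against the explanation, but that bound was set without regard to level: these RNAs had a median of 18.5 counts per library, close to the floor of 12, and 4 of them reached 1 CPM. Whether the histone transcripts counted here lacked a tail was not measured either. Selection and a change in the cells therefore cannot be told apart, and the cytokine treatment as a cause remains untested.

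Counts were 0 in every library of 1 group and at least 20 in every library of the other for 50 genes, 42 of them at 0 in the untreated cells. Assignment of reads between overlapping gene models is a possible explanation: 20% of these genes overlapped another tested gene on the same strand, against a median of 18% in 10000 sets matched on level (95% range 8% to 30%), so the share decides nothing either way. The 10 that overlapped lie in 8 separate loci, whose summed counts changed by a median log2 of 0.65 (95% bootstrap interval 0.033 to 4.67, untreated sums below the floor set to 12 counts), so as a set they leave moved reads open. Reads moved within an unchanged locus are argued against for 4 loci, where every treated library exceeded every untreated one by at least 0.68. These are the loci of TMEM239, AL035460 and C20orf141 (4.67), AL356234 (4.28), AC007991 with IDO1 (8.55) and TM4SF19-TCTEX1D2 (0.93). AL356234, AC007991 and TM4SF19-TCTEX1D2 held only 16.1%, 0.272% and 4.45% of their loci. The locus sums therefore cannot exclude that their counts are reads moved from a partner that rose. Which gene of such a locus changed stays open. For TMEM189-UBE2V1 (locus change 0.36), AC093525 (0.35), AL158151 (-0.25) and ABCF2-H2BE1 (0.033), moved reads and a change of the gene cannot be told apart, since each held at most 8.30% of its locus, and the treatment as a cause of the other switches remains untested.

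The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and 1 of the 10, the real split, gave the highest value of each count. It gave 7587 genes against at most 0 in the others, 1945 against at most 0 for genes changed at least 2-fold, 24 against at most 19 lists, and 302 against at most 162 annotation terms. All other splits part each group 2 to 1, so the treatment adds to the spread within their groups. With 0 genes called, these splits still gave 15 to 19 lists and 23 to 162 terms by camera with the preset correlation. They keep part of the treatment difference. The number of lists or terms called therefore sets the real split apart less sharply than the number of genes.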
